A study of Mus musculus with 2 samples.

How the data were processed

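Gene expression of spleen cells was measured in 2 libraries, 1 after grafting 2 times with HLA-A2.1 transgenic skin (ALLO) and 1 after grafting with wild-type skin (SYN). Groups were taken from the sample titles. The deposited files are whole-number counts of UMIs per gene and barcode with no normalization, made by the authors with Cell Ranger 6.0.2 per the file headers and the submitters' processing notes. The submitters' processing notes also name FastQC and the mm10 genome build. Aligner options and the annotation release are not given in the sources used here. The barcode lists hold no barcode under 500 UMIs. A dead cell removal kit with columns was used before capture, per the labels' protocols. Freezing, thawing and this column can change the shares of fragile cells.

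A barcode was kept with at least 200 genes and at most 10% of UMIs on mitochondrial genes, which removed 8 ALLO and 17 SYN barcodes for genes and 435 and 308 for mitochondrial UMIs. Scrublet, run per library in scanpy 1.11.5 with its automatic threshold, marked 115 ALLO cells (1.07%) and 378 SYN cells (2.17%) as doublets, which were removed. This left 10629 ALLO cells with 38266392 UMIs and 17081 SYN cells with 43085976 UMIs, of which 951 (8.95%) and 6203 (36.3%) held under 1000 UMIs. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen within each library and combined, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph 0.11.9) gave the clusters, with no integration of the libraries. Immunoglobulin and T cell receptor segments, mitochondrial genes and ribosomal protein genes were kept out of the variable genes. In a first clustering the T cell receptor gamma segments had been left in by mistake, and the cells were clustered again without them.

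Clusters were named "X-like" from fixed marker genes. CD4 T-like and CD8 T-like cells were clustered again for subsets. The marker genes, gene lists, filters, class comparisons, gene naming rule and most alternatives were set before the data were examined. The numeric limits for naming were not: they were set after the clusters and their shares had been seen. They ask that a cluster reach 0.5 of the highest cluster's level of a marker set (0.3 for B cell markers), with CD8 and CD4 levels of 0.3 and 0.5. Clusters with B cell markers above 0.2 and T cell markers above 0.15 together, and clusters with over 90% of cells from 1 library, stayed unnamed. The dividing-like cluster, at 0.315 and 0.233 for B and T cell markers, was an exception, because dividing markers were checked first. So did clusters with more markers of another class than of their own among the 10 leading genes, and shallow clusters with none of their own there. The choice of which lists and shares answer each comparison was also made after the values had been seen, by the subject of each class. The deposited barcodes come with no cell annotation used here, so a cell class is a rebuilt name.

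UMIs of a class were summed per library and divided by the class total to give CPM. The depth behind a class was 23347689 ALLO and 20792879 SYN UMIs in B-like cells, 4088825 and 6069772 in CD4 T-like cells, and 3970833 and 4094781 in CD8 T-like cells. Each sum has an exact Poisson interval, each ratio an exact conditional interval and each share a Clopper-Pearson interval, all at 95% and for counting error only (scipy 1.17.1, numpy 2.4.6). A ratio against 0 UMIs was computed against a floor of 3 counts. A gene list is summarised by the median log2 ratio of its members with at least 20 UMIs over both libraries. The percentile of that median among 10000 random lists of like expression, drawn from 20 expression bins, describes these libraries and is no test. The interval of a list median comes from 2000 Poisson redraws. Members at least 1.5-fold apart are counted as a description of size. The 12 highest and 12 lowest genes of B-like, CD4 T-like and CD8 T-like cells, and the 5 highest and 5 lowest of other classes with at least 100 cells in each library, were ranked by the bound of the ratio's interval nearest to 1 among genes with at least 50 UMIs. That ranking left out receptor and immunoglobulin segments, mitochondrial, ribosomal protein and predicted genes, and members of a list are named from the largest ratio down. Examples lower in a list, such as Tbx21, Prf1 and Stat3, and the genes named in clusters were chosen after their values were seen. Some genes that these rules name are not reported here.

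Shares of cells with a UMI were taken after each cell was thinned to 1000 UMIs, leaving out shallower cells, beside the same share in B-like cells as background. A plasma-like cell was assigned to the heavy chain constant gene with the most UMIs if it had at least 3 UMIs and at least 2 times the next gene. Its heavy and light variable segments were assigned by the same limits.

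The interval and list steps were tested on simulated Poisson sums drawn from the real totals. These draws follow the model that the intervals assume. They check the computation and leave out UMIs clumped in single cells, for which the intervals are too narrow. The intervals held the true ratio for 95.7% of 10908 genes in B-like, 95.8% of 9002 in CD4 T-like and 95.5% of 8433 in CD8 T-like cells. An interval clear of 1 was found for 93.9%, 73.1% and 70.1% of genes changed 1.5-fold, and for 100%, 98.5% and 97.0% of those changed 2-fold. Of 100 unchanged lists, 4, 4 and 8 lay outside the central 95% of random lists, and a list shifted by 0.5 lay at the 100th percentile in each class. Positions are from the mm10 annotation (GENCODE M21) matched by gene identifier.

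Alternatives covered the filters on cells, doublets, clustering resolution, naming per cell, clustering per library, denominators, scalings of CPM, minimum UMIs, thinning depths, assignment limits of constant genes and subset definitions. No group has a replicate, so tests between groups, leave-one-out checks and estimates of spread between animals could not be made. Germinal centre-like cells formed no cluster, so heavy chain classes are given for plasma-like cells.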

Results

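The title of the series asks about the Th17 pathway, the helper T cell programme built on interleukin 17, in the making of antibodies to HLA. Splenocytes of C57BL/6 recipients of tail skin were measured by droplet single-cell RNA sequencing of transcript 5′ ends. The ALLO group held 1 library, made after grafting of wild-type C57BL/6 at weeks 0 and 5 with skin of C57BL/6 mice carrying a human HLA-A2.1 transgene. The SYN group held 1 library, made after the same procedure with skin of wild-type C57BL/6 donors. Spleen cells were taken 4 weeks after the last graft, frozen, thawed and freed of dead cells on a column. The ALLO library held 39476214 UMIs over 11185 barcodes, with a median of 3113 UMIs per barcode. The SYN library held 45435231 UMIs over 17777 barcodes, with a median of 2036. The labels leave open how many animals a library holds. With 1 library per group no difference had a replicate check, no test could be made, and each comparison is between these 2 libraries and not between the treatments. Values in parentheses are exact 95% intervals, which cover counting error only, and n is 1 library per group throughout.

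B-like cells, the lineage that gives rise to antibody-secreting cells, were the largest named class, at 60.8% (59.9 to 61.7%) of 10629 kept ALLO cells and 35.3% (34.6 to 36.0%) of 17081 kept SYN cells. T-like cells made up 18.1% (17.4 to 18.9%) in ALLO and 14.3% (13.8 to 14.9%) in SYN, and NK-like cells 2.40% and 1.95%. Myeloid-like cells were fewer in ALLO, at 0.762% (0.606 to 0.946%) against 1.71% (1.52 to 1.92%), as were neutrophil-like cells at 0.160% against 0.779%, a ratio of 0.205 (0.116 to 0.341) that became 0.585 (0.258 to 1.25) with at least 500 genes per cell. Dividing-like cells, led by Mki67 and Top2a, were 0.894% and 0.831%, in a cluster that kept its name although it carried both B and T cell markers. These shares rest on how droplets with little RNA were treated. Unnamed clusters that carried B and T cell genes together, or drew over 90% of their cells from 1 library, held 3.31% of ALLO and 37.4% of SYN cells, and 34.4% and 81.3% of those had under 1000 UMIs. Among these, a cluster led by NK cell genes such as Ncr1 and Gzma held 0.0941% of ALLO and 2.75% of SYN cells. Another, led by Il1b and S100a9 among others, held 0 ALLO and 128 SYN cells. Both are left out of the NK-like and neutrophil-like shares above. Among cells of named classes alone, B-like cells were 72.7% of ALLO and 63.9% of SYN, while T-like cells were 21.7% against 26.0%, NK-like cells 2.87% against 3.53% and dividing-like cells 1.07% against 1.51%, all 3 in the opposite order. The other clusters left without a name were shallow B cell clusters with 6.48% and 3.40% of cells and with 0.649% and 0.141%. A cluster led by the T cell gene Themis held 1.53% and 1.61%, a cluster with B cell and haemoglobin genes 1.55% and 0.872%, and a cluster with B cell genes led by Il4i1 and Myc 2.85% and 1.34%. Of B-like cells and this last cluster together, it held 4.48% in ALLO and 3.66% in SYN, a ratio of 1.22 (1.03 to 1.46). Its cells are not part of the B-like class.

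Among T-like cells, CD8 T-like cells, the cytotoxic lineage, held a larger share in ALLO, and CD4 T-like cells, the helper lineage, a smaller one. CD8 T-like cells were 41.5% (39.3 to 43.8%) of 1926 ALLO T-like cells and 33.6% (31.7 to 35.5%) of 2450 in SYN, and CD4 T-like cells 55.0% (52.8 to 57.3%) and 63.5% (61.6 to 65.4%). Regulatory T-like cells, a suppressive lineage with Foxp3 as its master regulator, were 16.7% (14.5 to 19.1%) of 1060 ALLO CD4 T-like cells and 10.7% (9.18 to 12.3%) of 1556 in SYN. Th1-like cells, the interferon gamma producers led here by Ccl5, Cxcr3 and Ifng, were 20.2% (17.8 to 22.7%) and 12.98% (11.4 to 14.8%). Naive CD4 T-like cells were 41.5% (38.5 to 44.5%) against 53.8% (51.3 to 56.3%), an order that turned when each library was clustered on its own, to a ratio of 3.85 (3.29 to 4.53). Over cells of named classes, the ALLO over SYN ratio was 1.03 (0.935 to 1.14) for CD8 T-like and 0.723 (0.668 to 0.782) for CD4 T-like cells. There it was 1.13 (0.910 to 1.41) for regulatory, 1.12 (0.923 to 1.37) for Th1-like and 0.558 (0.496 to 0.627) for naive CD4 T-like cells. Over kept cells these ratios were, in turn, 1.56, 1.09, 1.71, 1.70 and 0.845, so they depend on the denominator. No cluster was named for follicular helper or Th17 cells, and the Th1-like cluster also held the highest levels of follicular helper, Th17, effector CD8 and NK markers among the CD4 T-like subclusters. Cd8a or Cd8b1 UMIs were present in 9 of 214 ALLO and 26 of 202 SYN Th1-like cells. Unnamed CD4 T-like subclusters included one led by Ifit1, Ifit3 and Isg15, interferon-induced genes, with 4.34% (3.19 to 5.75%) against 1.67% (1.09 to 2.44%). Another, led by Sox4, held 15.1% and 19.2%, and one led by Xcl1 held 2.17% and 1.74%. A subcluster that mixed CD4 T and B cell genes was left out, with 5.19% of ALLO and 4.89% of SYN cells of these clusters. With cells thinned to 1000 UMIs, Foxp3 was detected in 63 of 1002 ALLO cells, 6.29% (4.86 to 7.97%), and in 68 of 1512 SYN cells, 4.50% (3.51 to 5.67%), with 58 and 44 shallower cells left out. Without thinning the shares were 11.5% and 8.35%, and in thinned B-like cells, the background, 0.0782% and 0.0673%. Median depths were 3796 and 3814.5 UMIs in CD4 T-like cells and 3182.5 and 3075 in B-like cells.

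**Figure D1:**
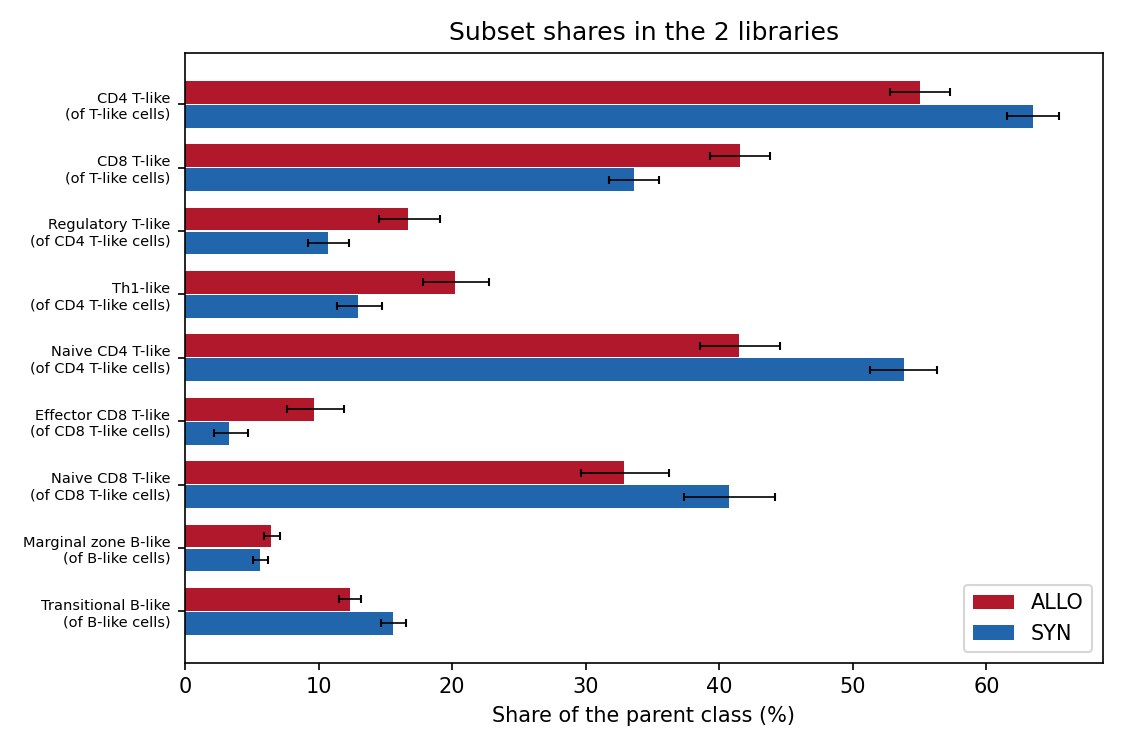
Shares of each cell class within its parent class, in percent, in the ALLO library (red) and the SYN library (blue), with exact 95% intervals that cover counting error only. Effector CD8 T-like cells were 9.63% against 3.28%, regulatory T-like cells 16.7% against 10.7% and naive CD4 T-like cells 41.5% against 53.8%, the last in the opposite order when each library was clustered on its own.

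In CD4 T-like cells, genes of activated helper programmes were higher in ALLO and genes of the naive state lower. Follicular helper genes, which serve help to B cells, had a median log2 ratio of 0.31 (0.19 to 0.49), at the 100th percentile of 10000 expression-matched random lists, with 4 of 17 measured members at least 1.5-fold higher and 0 lower. Their examples were Il4, a cytokine that drives class switching, at 3.18-fold (1.64 to 6.49), the CD30 ligand gene Tnfsf8 at 2.17-fold (1.81 to 2.60), the inhibitory receptor gene Pdcd1 at 1.86-fold (1.48 to 2.35) and the lineage regulator Bcl6 at 1.65-fold (1.21 to 2.25). Th1 genes had a median of 0.38 (0.25 to 0.53, 100th percentile), with 5 of 14 at least 1.5-fold higher and 0 lower. Ifng, interferon gamma itself, was at 26.4 CPM in ALLO and 7.08 in SYN, 3.73-fold (2.60 to 5.44), Ccl5 at 2.31-fold (2.10 to 2.55) and Cxcr3 at 1.65-fold (1.38 to 1.98), while the Th1 regulator Tbx21 was at 1.14-fold (0.685 to 1.89). Regulatory T genes had a median of 0.26 (0.18 to 0.42, 100th percentile), with 3 of 15 at least 1.5-fold higher and 2 lower. Il2ra, the high-affinity interleukin 2 receptor chain, was 1.81-fold (1.49 to 2.21), Tnfrsf4 1.68-fold (1.44 to 1.96) and Foxp3 1.34-fold (1.14 to 1.58). T cell inhibitory receptors, a list that shares Pdcd1, Tox, Btla and Ctla4 with those above, had a median of 0.68 (0.51 to 0.96, 100th percentile). At least 1.5-fold higher were 6 of 8, among them Lag3 at 3.10-fold (2.16 to 4.50) and Cd160 at 2.56-fold (1.48 to 4.55). Naive T genes had a median of −0.18 (−0.21 to −0.10), below every random list, and Il7r, the survival cytokine receptor of resting T cells, was 1.51-fold lower (1.42 to 1.60). Th2 genes had a median of −0.20 (−0.36 to 0.05, percentile 3.03) although Il4 belongs to that list too. These medians and the subset shares are one observation, since the named subsets are defined by many of the same genes. B cell genes moved with them in CD4 T-like cells, with a median of 0.45 (0.30 to 0.61) and 12 of 12 members higher in ALLO, for example the class II gene H2-Aa at 1.75-fold (1.42 to 2.17), and haemoglobin and neutrophil genes had a median of 2.69 (1.89 to 3.81), where 1 ALLO cell held 116 of 128 ALLO haemoglobin UMIs.

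The single genes with the largest ALLO excess in CD4 T-like cells included Sostdc1, a secreted antagonist of BMP and Wnt signals, at 37.2 against 4.45 CPM, 8.36-fold (5.52 to 13.1). Sostdc1 was also among the fixed follicular helper markers used to name clusters. Its 152 ALLO and 27 SYN UMIs lay in the Th1-like cells, the cluster that also held the highest follicular helper marker levels. Whether its cells are Th1 or follicular helper cells was not tested. The follicular helper genes Cxcr5 and Pdcd1 were detected together in 3 of 1002 thinned ALLO CD4 T-like cells, 0.299% (0.0618 to 0.872%). In SYN they were detected together in 0 of 1512 (0 to 0.244%), so the intervals overlapped. Gzmk, a granzyme gene, was 7.59-fold higher (3.67 to 17.6), Cxcl10, an interferon-induced chemokine gene, 6.62-fold (3.59 to 13.2), and the calcium channel gene Cacna1d 7.31-fold (3.99 to 14.5). Camk2b was 5.50-fold higher (3.18 to 10.0), the transcription factor gene Bhlhe40 4.14-fold (3.11 to 5.57) and Spp1, which encodes osteopontin, 3.81-fold (2.67 to 5.53). Lower in ALLO were Gzma, which encodes granzyme A, by 12.9-fold (6.09 to 32.7), the mitosis genes Birc5 by 5.39-fold (2.58 to 13.02), Mki67 by 2.85-fold (1.76 to 4.84) and Ube2c by 2.51-fold (1.55 to 4.22), and Cd8a by 4.04-fold (2.05 to 8.86). Bbc3, which encodes the death-promoting protein PUMA, was 2.53-fold lower (1.89 to 3.44), Lgals3 2.80-fold (1.68 to 4.90) and the stress gene Ddit4 1.56-fold (1.42 to 1.71). Lmnb2, a nuclear lamin gene, was 2.26-fold lower (1.40 to 3.77), Cpt1a, the entry enzyme of mitochondrial fatty acid oxidation, 1.82-fold (1.39 to 2.43), and Spata5l1 1.87-fold (1.38 to 2.57). In the Th1-like cells alone, Gzma was at 2.30 CPM in ALLO and 133 in SYN from 2 and 110 UMIs, a ratio of 0.0172 (0.00206 to 0.0638), and Cd8b1 was 10.5-fold lower (5.32 to 23.8). In regulatory T-like cells Penk, which encodes proenkephalin, was 5.24-fold lower (2.82 to 10.6) and the calcium-binding protein gene S100a6 2.53-fold lower (2.14 to 3.02). Without cells holding a UMI of the other co-receptor, a choice made after the data were seen, the log2 ratios of Birc5 and Ube2c turned to 0.24 and 0.77, and with at least 500 genes per cell that of Mki67 turned to 0.53. In Th1-like cells drawn at a coarser resolution, which held no Sostdc1 UMI in either library, Cacna1d and Bhlhe40 turned to −1.89 and −0.01, and Gzma to 1.28.

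The Th17 programme itself was scarce in both libraries. Il17a, which encodes interleukin 17A (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496, plus strand, mm10), had 3 UMIs in 1 ALLO CD4 T-like cell of 1060 and 0 UMIs in 1556 SYN cells, which at a floor of 3 counts allows up to 0.193% of cells with a UMI. Among all kept cells of any class Il17f UMIs lay in 2 ALLO and 3 SYN cells and Il22 UMIs in 0 and 2. In CD4 T-like cells Il23r, the interleukin 23 receptor gene, had 5 UMIs in 4 ALLO cells against 1 UMI in 1 SYN cell, a ratio of 7.42 (0.831 to 351), and Il21 17 UMIs against 21, a ratio of 1.20 (0.595 to 2.39). A UMI of any of 11 fixed Th17 cell markers was found in 21 of 1002 ALLO CD4 T-like cells thinned to 1000 UMIs, 2.10% (1.30 to 3.19%), and in 23 of 1512 in SYN, 1.52% (0.967 to 2.27%), with 58 and 44 shallower cells left out. Without thinning the shares were 4.62% and 4.37%. Over all T-like cells, thinned, the order was the opposite, at 1.67% (1.14 to 2.36%) in ALLO and 1.75% (1.27 to 2.36%) in SYN. In B-like cells, with median depths of 3182.5 and 3075 UMIs beside 3796 and 3814.5 in CD4 T-like cells, the thinned shares were 8.10% and 6.82%, mostly from Ccr6, a chemokine receptor gene of both B and Th17 cells, at 7.20% and 6.43%. B cells express Ccr6 themselves, so this share is no background for CD4 T-like cells. The intervals of the CD4 T-like shares overlapped, with a ratio of 1.38 (0.725 to 2.60), so a difference in cells with a Th17 marker was not detectable at this depth. The Th17 differentiation list had a median log2 ratio of 0.12 (−0.06 to 0.23, percentile 96.5) in CD4 T-like cells, with 0 of 14 members 1.5-fold apart, and IL-17 and IL-23 signalling genes −0.01 (−0.12 to 0.14). With cells thinned to 1000 UMIs these medians were higher, at 0.32 and 0.15. Rora, a nuclear receptor gene used by Th17 and other memory cells, was 29.8 against 26.4 CPM, Maf 1.33-fold (1.10 to 1.60), Hif1a 1.31-fold (1.16 to 1.47) and Stat3, the signal carrier of interleukins 6 and 23, 0.903-fold (0.7998 to 1.02). With a group of 6 Th17 genes chosen after their counts were seen, 8 of 1002 ALLO and 4 of 1512 SYN cells held a UMI, a ratio of 3.02 (0.809 to 13.7), beside 0 of 6392 and 1 of 5940 B-like cells.

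CD8 T-like cells of ALLO held more effector cells and higher cytotoxic genes. Effector CD8 T-like cells were 9.63% (7.67 to 11.9%) of 800 ALLO and 3.28% (2.17 to 4.74%) of 823 SYN CD8 T-like cells, and naive CD8 T-like cells 32.9% (29.6 to 36.2%) and 40.7% (37.3 to 44.2%). Cytotoxic genes had a median log2 ratio of 0.45 (0.27 to 0.50, 100th percentile), with 7 of 17 at least 1.5-fold higher and 0 lower. Gzma was at 232 CPM in ALLO and 57.9 in SYN, 4.01-fold (3.47 to 4.64), Cx3cr1, a chemokine receptor gene of circulating effectors, 3.97-fold (2.40 to 6.86), the senescence-associated receptor gene Klrg1 3.84-fold (2.53 to 6.00) and Gzmb, which encodes granzyme B, 2.72-fold (1.84 to 4.11). Ifng was 1.97-fold (1.55 to 2.51), while the perforin gene Prf1 was 1.19-fold (0.974 to 1.45). Of the activation and memory genes, with a median of 0.19 (0.13 to 0.25, 100th percentile), 3 of 16 were at least 1.5-fold higher, namely Lgals3 at 2.46-fold (1.60 to 3.87), S100a4 at 2.21-fold (1.78 to 2.76) and S100a6 at 1.79-fold (1.63 to 1.97). The effector migration gene S1pr5 was 2.84-fold (1.92 to 4.28) and Zeb2, a transcription factor gene of terminal effectors, 2.29-fold (1.67 to 3.18). The effector cluster is led by Gzma, Klrg1, S1pr5, Cx3cr1 and Gzmb, so its size and these values describe the same cells. Inhibitory receptors had a median of −0.11 (−0.48 to 0.03), unlike in CD4 T-like cells, a difference that was not tested, and Pdcd1 was at 4.53 against 8.79 CPM, a ratio of 0.516 (0.276 to 0.932). Naive T genes had a median of −0.16 (−0.23 to −0.11, percentile 0.04). NF-kB response genes had a median of −0.28 (−0.37 to −0.11, percentile 0.13), with Nfkbia, the pathway's feedback inhibitor, at a ratio of 0.692 (0.638 to 0.749).

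Other genes lower in ALLO CD8 T-like cells were Bbc3 by 2.12-fold (1.72 to 2.62), Art2b, an ADP-ribosyltransferase gene of resting T cells, by 2.15-fold (1.59 to 2.94), Bcl6 by 2.25-fold (1.39 to 3.75) and Trnp1 by 3.09-fold (1.73 to 5.81). Cd4 UMIs were 2.26-fold lower (1.42 to 3.70), from 27 UMIs in ALLO and 63 in SYN. The B cell gene list had a median of 0.11 (−0.13 to 0.18), and haemoglobin genes a median of −6.70 (−7.05 to −5.32), which rests on 1 SYN cell with 539 of the 579 haemoglobin UMIs of the SYN class. Subclusters of CD8 T-like cells with NK receptor genes held 16.9% and 22.1%, gamma delta T-like cells 3.13% and 3.65%, and the unnamed ones 14.3% and 10.6%, 20.1% and 14.8%, and 3.13% and 4.86%. The subcluster mixed with B cell genes that was left out held 6.54% and 4.97% of the cells of these clusters. With members of at least 100 UMIs alone, the cytotoxic median was 0.25.

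Type I interferon response genes, as a list, were higher in ALLO in B-like, CD4 T-like, CD8 T-like and NK-like cells. The type I interferon list had a median log2 ratio of 0.45 (0.35 to 0.51) in B-like cells, 0.45 (0.35 to 0.60) in CD4 T-like cells and 0.20 (0.07 to 0.37) in CD8 T-like cells, each at the 100th percentile. In NK-like cells it was 0.28 (0.07 to 0.54, percentile 99.8). At least 1.5-fold higher were 5 of 19 members in B-like, 7 of 19 in CD4 T-like and 5 of 19 in CD8 T-like cells, with 0 lower in each. Ifit3, which encodes an interferon-induced antiviral protein, was 2.49-fold (1.99 to 3.13) in B-like, 6.55-fold (4.09 to 10.9) in CD4 T-like and 3.78-fold (2.22 to 6.77) in CD8 T-like cells. Isg15, a ubiquitin-like modifier gene, was 1.36-fold (1.17 to 1.60), 2.13-fold (1.77 to 2.56) and 1.90-fold (1.43 to 2.54), and Usp18, which encodes the enzyme that removes ISG15, 2.17-fold (1.68 to 2.83) in B-like cells. Interferon gamma response genes had medians of 0.15 (0.08 to 0.22) in B-like, 0.23 (0.11 to 0.34) in CD4 T-like and −0.01 (−0.13 to 0.05) in CD8 T-like cells. A B-like cluster led by Ifit3, Usp18 and Isg15 held 0.603% (0.429 to 0.824%) of ALLO and 0.365% (0.229 to 0.552%) of SYN B-like cells. T cell genes moved against this list in B-like cells, with a median of −0.64 (−0.93 to −0.51), and haemoglobin and neutrophil genes had a median of 0.50 (−0.01 to 1.29) there, with 241 and 102 of the 502 ALLO haemoglobin UMIs in 1 cell each.

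**Figure D2:**
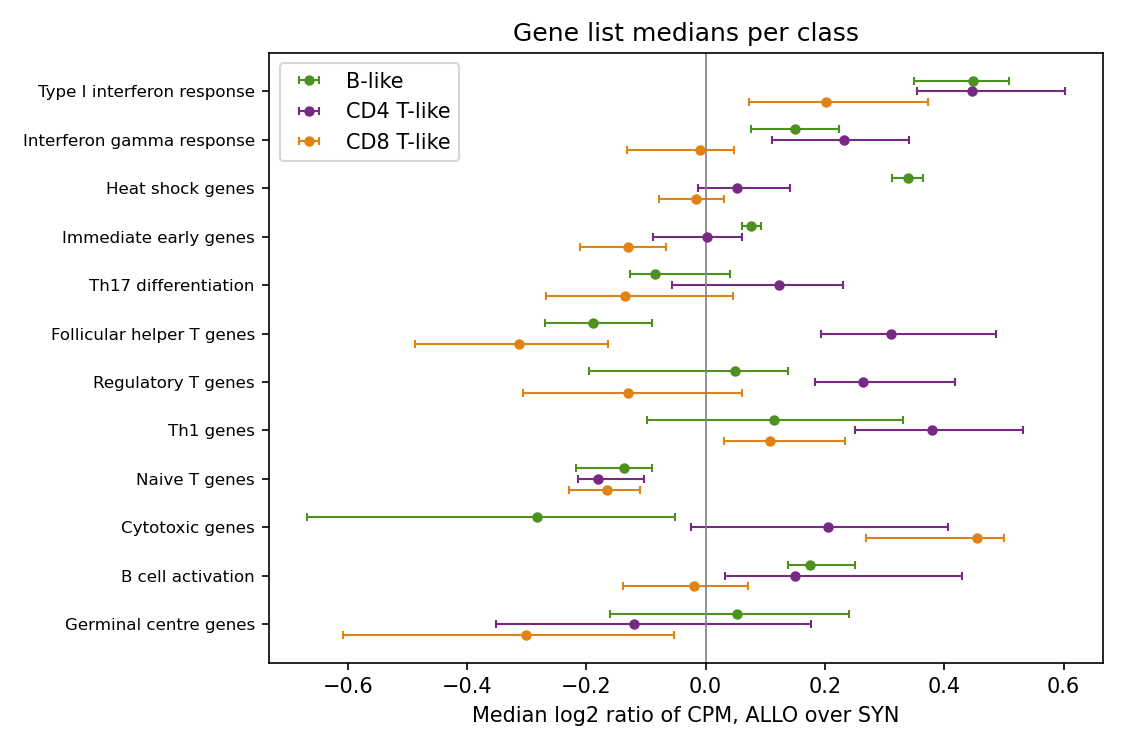
Median log2 ratio of CPM, ALLO over SYN, of the measured members of each gene list in B-like (green), CD4 T-like (purple) and CD8 T-like cells (orange), with intervals that cover counting error only. Type I interferon medians were 0.45, 0.45 and 0.20, the cytotoxic median in CD8 T-like cells 0.45 and the Th17 differentiation median in CD4 T-like cells 0.12.

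B-like cells of ALLO showed higher stress and activation genes. Follicular B-like cells, the recirculating majority, were 80.6% (79.6 to 81.5%) of 6464 ALLO and 78.4% (77.4 to 79.5%) of 6026 SYN B-like cells, marginal zone B-like cells, the blood-facing innate-like subset, 6.47% (5.88 to 7.09%) and 5.63% (5.06 to 6.24%), and transitional B-like cells, recent arrivals from bone marrow, 12.3% (11.6 to 13.2%) and 15.6% (14.7 to 16.5%). B cell activation genes had a median log2 ratio of 0.17 (0.14 to 0.25, 100th percentile), with 2 of 20 at least 1.5-fold higher and 0 lower. Those were the chemokine genes Ccl3 at 4.22-fold (2.39 to 7.92) and Ccl4 at 2.03-fold (1.46 to 2.86), followed by Irf4, a regulator of plasma cell differentiation, at 1.49-fold (1.41 to 1.58) and Myc at 1.37-fold (1.29 to 1.46). Heat shock genes had a median of 0.34 (0.31 to 0.36, 100th percentile), with 4 of 10 at least 1.5-fold higher, such as Hsph1 at 1.64-fold (1.48 to 1.81) and Dnajb1 at 1.55-fold (1.47 to 1.63). Germinal centre genes, of the sites of antibody maturation, had a median of 0.05 (−0.16 to 0.24, percentile 90.9). Plasma cell and secretory genes had a median of 0.04 (−0.03 to 0.06) and memory and atypical B genes 0.06 (−0.05 to 0.21). With cells thinned to 1000 UMIs the germinal centre median turned to −0.18 and the memory and atypical median was 0.25.

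Single B-like genes higher in ALLO were Xlr at 3.63-fold (1.95 to 7.26), the small heat shock protein gene Hspb1 at 4.06-fold (1.94 to 9.49), Mtus2 at 3.43-fold (1.83 to 6.87), Sdc3 at 3.24-fold (1.77 to 6.35) and Cd59a, which encodes a complement inhibitor, at 3.48-fold (1.77 to 7.49). Lower in ALLO were Capn11 by 7.11-fold (3.50 to 16.3), the heavy chain constant gene Ighg1 by 4.49-fold (2.35 to 9.29), Zfp53 by 2.13-fold (1.85 to 2.45) and Plcl1 by 3.37-fold (1.76 to 6.88). The Ighg1 ratio rests on 12 ALLO and 48 SYN UMIs. Whether a few cells held most of them was not examined, and its interval would then be too narrow. The cyclin gene Ccnd3, needed for B cell expansion, was at 98.2 against 170 CPM, 1.73-fold lower (1.64 to 1.83), Ddit4 1.74-fold (1.61 to 1.89), the adaptor gene Sla 1.69-fold (1.58 to 1.81), Rflnb 1.73-fold (1.58 to 1.89) and Acp5, which encodes an acid phosphatase, 1.64-fold (1.57 to 1.71). The histone gene Hist1h2ab was 2.41-fold lower (1.58 to 3.74). The T cell genes Thy1 and Il7r were 2.65-fold (1.78 to 4.03) and 2.44-fold lower (1.71 to 3.54) and belong to the set of T cell genes that marks T cell RNA in B-like droplets. When each library was clustered on its own the ratios of marginal zone and transitional shares came to 5.01 and 0.317, but at resolution 0.5 the marginal zone ratio was 0.742 and with at least 500 genes the transitional ratio 1.01. The follicular ratio lay between 0.772 and 1.47 over the alternatives.

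Antibody-secreting cells differed in heavy chain class in a way that rested on 1 pair of variable segments per library. Plasma-like cells were 0.470% (0.349 to 0.620%) of kept ALLO cells and 0.334% (0.253 to 0.432%) of kept SYN cells, a ratio of 1.41 (0.945 to 2.10). Over cells of named classes the ratio was 0.931 (0.624 to 1.39), and over 12 alternatives it ran from 0.854 to 4.85, so its direction stays open. Of 50 ALLO and 57 SYN plasma-like cells, 46 and 53 could be assigned to a constant gene. Ighm, the IgM class, was assigned to 27 ALLO cells, 58.7% (43.2 to 73.0%), and to 8 SYN cells, 15.1% (6.75 to 27.6%). Igha, the IgA class of mucosal responses, was assigned to 15 ALLO cells, 32.6% (19.5 to 48.0%), and to 42 SYN cells, 79.2% (65.9 to 89.2%), and IgG genes to 4 and 3 cells. In ALLO, 19 of 45 cells with both segments, 42.2% (27.7 to 57.8%), used Ighv8-12 with Igkv12-44, and all 19 were Ighm. In SYN, 31 of 55 cells, 56.4% (42.3 to 69.7%), used Ighv3-6 with Igkv10-96, of which 29 were Igha and 2 not assigned. Each pair was seen in 0 cells of the other library, and the next most frequent pair held 2 cells in ALLO and 1 in SYN, among 23 and 25 pairs. Without both pairs, a check chosen after the data were seen, Ighm was 8 of 27 cells in ALLO, 29.6% (13.8 to 50.2%), and 8 of 24 in SYN, 33.3% (15.6 to 55.3%), and Igha 55.6% (35.3 to 74.5%) and 54.2% (32.8 to 74.4%), so the difference was gone. Over summed UMIs, Ighm was 41.1% of heavy chain constant UMIs in ALLO and 30.3% in SYN, and Igha 57.4% and 62.7%. The ALLO over SYN ratio of the Ighm share was 3.89, and it ran from 0.889 to 9 over 10 alternatives. That of the Igha share was 0.411 and ran from 0.219 to 1.03. On mm10, Ighv8-12 lies on chromosome 12 at 115647945 to 115648387 and Ighv3-6 at 114288152 to 114288582, Igkv12-44 on chromosome 6 at 69814631 to 69815154 and Igkv10-96 at 68631963 to 68632442, all on the minus strand. In B-like cells the segments were at like shares in both libraries, for example Ighv8-12 in 2.40% (2.04 to 2.80%) and 2.46% (2.08 to 2.88%). Segments are near-identical copies of each other, so counts can be split between them, and junction sequences were not used here, so cells of 1 pair need not be 1 clone.

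**Figure D3:**
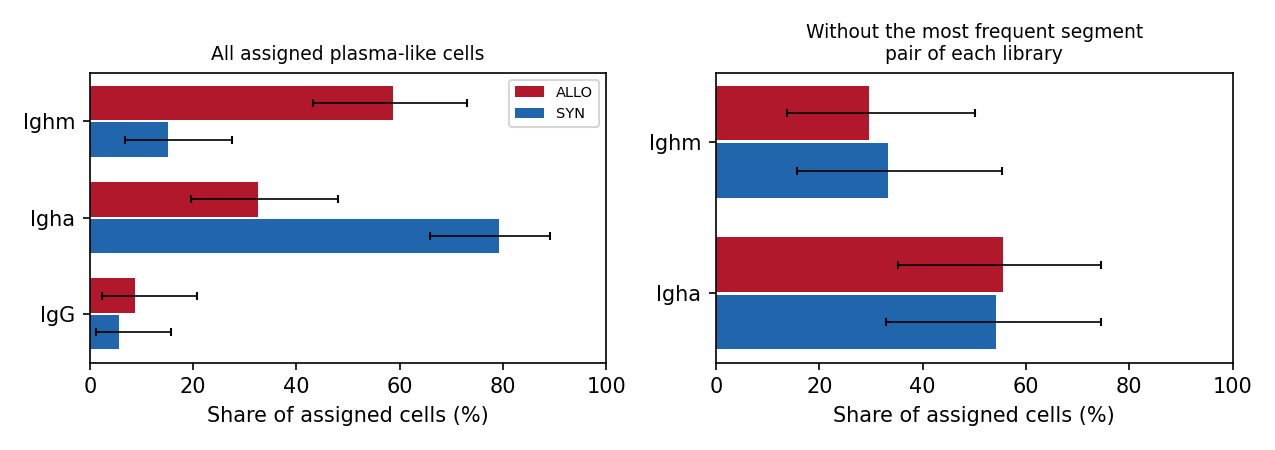
Share of assigned plasma-like cells per heavy chain constant gene, in percent, in the ALLO library (red) and the SYN library (blue), over all assigned cells (left) and without the most frequent segment pair of each library (right), with exact 95% intervals that cover counting error only. Ighm was 58.7% against 15.1% over all assigned cells, and 29.6% against 33.3% without the pairs.

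In NK-like cells, innate cytotoxic lymphocytes with 255 ALLO and 333 SYN cells, cytotoxic genes were alike, with a median log2 ratio of 0.00 (−0.06 to 0.10). Plac8 was 3.85-fold higher (2.09 to 7.48), the interferon-induced gene Ifi27l2a 2.65-fold (1.65 to 4.35) and Camk2b 6.02-fold (3.46 to 11.1). Larp4, an RNA-binding protein gene, was 3.57-fold lower (1.84 to 7.57), the receptor gene Notch2 2.69-fold (1.62 to 4.65) and Tob1, an antiproliferative gene, 2.27-fold (1.504 to 3.53). B cell genes had a median of 0.15 (0.04 to 0.25) in these cells. With cells thinned to 1000 UMIs Ifi27l2a turned to a log2 ratio of −0.25.

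A few genes were shifted alike in B-like, CD4 T-like and CD8 T-like cells, among them the inducible heat shock genes. Some predicted genes, which the naming rule leaves out, were shifted more. Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, mm10), which encodes the stress-induced chaperone HSP70, was at 35.9 against 2.98 CPM in B-like cells, 12.04-fold higher in ALLO (9.29 to 15.8), and 8.38-fold (6.01 to 11.9), 8.73-fold (4.90 to 16.9) and 9.97-fold (4.74 to 24.2) higher in CD4 T-like, CD8 T-like and NK-like cells. Its neighbour and near-identical copy Hspa1b, at 34956436 to 34959238, was 11.8-fold (9.69 to 14.5), 7.58-fold (6.00 to 9.66), 4.63-fold (3.31 to 6.60) and 4.23-fold (2.71 to 6.79) higher, and counts may be split between the copies. Cdk5rap1, which encodes a tRNA-modifying enzyme of mitochondria (chromosome 2, 154335380 to 154373010), was 6.54-fold (5.40 to 7.97), 8.25-fold (5.70 to 12.3) and 7.60-fold (4.69 to 13) higher in B-like, CD4 T-like and CD8 T-like cells. Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962), had 191 UMIs in ALLO B-like cells and 0 in SYN B-like cells. Slc15a2 is not among the 18 genes, counted next, that were shifted alike in all 3 classes. Of 9248 genes measured in B-like, CD4 T-like and CD8 T-like cells, 18 were shifted at least 1.5-fold in the same direction in all 3 classes, 16 higher and 2 lower in ALLO, of which 7 are predicted genes. By a looser rule, 64 were at least 1.5-fold higher in 1 class and at least 1.5-fold lower in another, so the 2 counts are not alike.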

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

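The share of named cells, the minimum of 1000 UMIs, the co-receptor filter, the naming of clusters of 1 library, the receptor gamma segments, the removal of segment pairs and the group of 6 Th17 genes are tests chosen after the results were seen. So was the choice of which results answer a comparison. With 1 library per group leave-one-out checks could not be made. No paired analysis was possible because each group has 1 library and no test was run. Across the alternatives run, shares kept their value within the counting interval in 195 cases, moved in 39 and reversed in 11. The lists named for a class stayed in 299 cases and moved in 21. The other lists stayed in 1530, moved in 122 and reversed in 12. Named genes stayed in 1916, moved in 176 and reversed in 21. Some cases counted as moved also changed direction, so the reversed counts leave out such changes. Thinned to 1000 UMIs, the germinal centre median in B-like cells went from 0.05 to −0.18. The IL-17 and IL-23 signalling median in CD4 T-like cells went from −0.01 to 0.15 there. The marginal zone ratio went from 1.15 to 0.742 at resolution 0.5, and the plasma-like ratio from 1.41 to 0.854 with at least 1000 UMIs. The ALLO over SYN ratio of regulatory T-like cells stayed between 1.33 and 1.57 over 15 alternatives, that of effector CD8 T-like cells between 2.35 and 3.30 and that of CD8 T-like cells between 1.24 and 1.36. These are ratios of shares of the parent class, and none of these alternatives took them over cells of named classes. The type I interferon medians stayed between 0.36 and 0.51 in B-like cells and 0.09 and 0.29 in CD8 T-like cells, and the Th1 median in CD4 T-like cells between 0.35 and 0.52. Little can be said of the rarest transcripts, since Il17a, Il17f and Il22 each have 3 UMIs or fewer per library.

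Values below are ALLO over SYN ratios of shares, or log2 ratios for genes and lists, and the cause of each change was not tested unless stated. Scaled to a median log2 ratio of 0, the medians were 0.10 for secretory genes in B-like cells and, in CD8 T-like cells, 0.28 for activation and memory, 0.54 for cytotoxic and 0.078 for interferon gamma response genes. Thinned to 1000 UMIs, the medians in B-like cells were 0.27 for activation, −0.18 for germinal centre and 0.25 for memory and atypical genes. In CD4 T-like cells they were 0.32 for Th17 differentiation, 0.15 for IL-17 and IL-23 signalling, 0.53 for follicular helper, −0.41 for Th2, 0.35 for type I interferon, 0.11 for interferon gamma and −0.0084 for inflammatory myeloid genes, with Birc5 at 0.18 and Ube2c at 0.59. In CD8 T-like cells they were 0.60 for cytotoxic and 0.051 for immediate early genes, and in NK-like cells Ifi27l2a was −0.25 and memory and atypical genes −0.14. As means over cells, follicular helper genes in CD4 T-like cells were 0.67, and in CD8 T-like cells activation and memory genes were 0.29, cytotoxic genes 0.60 and B cell genes −0.023. With no minimum, inflammatory myeloid genes were −0.31 in B-like cells and memory and atypical genes −0.012 in CD8 T-like cells. With at least 100 UMIs cytotoxic genes were 0.25 in CD8 T-like cells.

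With 6 grouped genes the Th17 share ratio was 3.02. Over summed UMIs Ighm was 1.36 and Igha 0.915, and without the most frequent pair of each library 0.889 and 1.03, because this leaves out the 19 Ighm cells and 29 Igha cells of those pairs. Among named cells alone, where the shallow SYN droplets leave the denominator, the ratios were B-like 1.14, T-like 0.834, NK-like 0.813, plasma-like 0.931, myeloid-like 0.294 and dividing-like 0.710. With classes from marker UMIs per cell they were B-like 1.18, T-like 1.15, NK-like 0.729 and CD4 T-like 0.941. Without cells of the other co-receptor Birc5 and Ube2c in CD4 T-like cells were 0.24 and 0.77, and the co-receptor genes that this filter removes gave no value.

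At resolution 0.5 the marginal zone ratio was 0.742 and the transitional 0.961, and in Th1-like cells, where Sostdc1 and Birc5 had no UMI and gave no value, Cacna1d was −1.89, Bhlhe40 −0.0053 and Gzma 1.28. At resolution 2 the B-like ratio was 1.66, the follicular 0.827, memory and atypical genes in B-like cells 0.25, B cell genes in CD8 T-like cells −0.040 and Ms4a6c in marginal zone B-like cells 0.059. With at least 500 genes the ratios were B-like 1.07, T-like 0.948, NK-like 0.888, plasma-like 0.918, neutrophil-like 0.585, follicular 0.909, marginal zone 1.52 and transitional 1.01. There memory and atypical genes in B-like cells were 0.25, in CD4 T-like cells Birc5 was 2.58, Mki67 0.53 and Ube2c 1.64, in transitional B-like cells S100a6 was −0.10, and in Th1-like cells Birc5 was 2.62 and Mki67 0.80. With at least 1000 UMIs the ratios were B-like 1.20, T-like 0.880, NK-like 0.791, plasma-like 0.854 and follicular 0.772, with Mki67 at 0.17 and Ube2c at 0.95 in CD4 T-like cells and Ms4a6c at 0.31 in marginal zone B-like cells.

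With at most 5% mitochondrial UMIs the follicular ratio was 0.772 and MHC class II genes in NK-like cells −0.028. With no cell filter the follicular ratio was 0.835 and Ube2c in CD4 T-like cells 1.40. With doublets kept the ratios were B-like 1.61, follicular 0.986 and transitional 0.954. There memory and atypical genes in B-like cells were 0.22, Tmem176a in CD8 T-like cells 0.028, and in NK-like cells MHC class II genes −0.10 and B cell genes −0.14. With clusters of 1 library named the ratios were B-like 1.20, follicular 1.47, marginal zone 1.65 and transitional 0.341, and erythrocyte and neutrophil genes in B-like cells −0.11. With receptor gamma segments among the variable genes the follicular ratio was 0.953, erythrocyte and neutrophil genes in B-like cells −0.69 and Tmem176a in CD8 T-like cells 0.040. With each library clustered on its own the ratios were B-like 1.15, plasma-like 4.85, myeloid-like 0.663, marginal zone 5.01, transitional 0.317, Th1-like 1.26, naive CD4 T-like 3.85 and naive CD8 T-like 0.641.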

Other observations

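The tests of mixed RNA, of doublets, of thinned depth, free RNA, the largest NK share and cells with Cd8b1 for the cytotoxic genes, and of a handling response were chosen after the results were seen. Further ALLO over SYN differences were seen within subsets. Each gene named here moved in the same direction in its parent class, Myc within counting error, and whether a difference is particular to a subset was not tested. In marginal zone B-like cells Nr4a2, an orphan receptor gene induced by antigen receptor signals, was 2.77-fold higher in ALLO (1.76 to 4.51) and the interferon-induced gene Rtp4 3.03-fold (1.62 to 6.08), while the lipid carrier gene Apoe was at 295 against 496 CPM, 1.68-fold lower (1.52 to 1.86). In transitional B-like cells Tlr7, the endosomal sensor of single-stranded RNA, was 2.55-fold higher (1.59 to 4.18) and Idi1, an enzyme gene of sterol synthesis, 2.98-fold (1.69 to 5.46), while Ccnd3 was 1.72-fold lower (1.52 to 1.96). In regulatory T-like cells Bhlhe40 was 2.31-fold higher (1.39 to 3.93) and Myc 2.91-fold lower (1.82 to 4.81), with Vim, the intermediate filament gene, 1.97-fold lower (1.66 to 2.33). In naive CD4 T-like cells Bbc3 was 2.79-fold lower (1.82 to 4.43), near its value in all CD4 T-like cells.

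Genes of basic metabolism differed little. Oxidative phosphorylation genes had medians of 0.03, −0.01 and 0.03 in B-like, CD4 T-like and CD8 T-like cells and glycolysis genes −0.05, −0.09 and −0.02, with 0 members 1.5-fold apart in any of these. MHC class I genes had medians of 0.03, 0.02 and −0.08. MHC class II genes were level in B-like cells, with a median of 0.02, and had a median of 0.37 (0.19 to 0.60) in CD4 T-like cells, where the B cell genes, a list that shares members with it, were also higher. Light chain constant genes in CD4 T-like cells had a median of 0.77 (0.37 to 1.06). Cell cycle genes had medians of 0.01, 0.01 and 0.06, but 5 of 17 members were at least 1.5-fold lower in CD4 T-like cells, and in Th1-like cells the median was −0.48 (−0.65 to −0.31). With at least 500 genes per cell Mki67 and Birc5 of the Th1-like cells turned to 0.80 and 2.62.

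A stretch of the T cell receptor alpha locus was read almost only in ALLO, a feature singled out after its values were seen. From Trav8d-2 to Trav11n (chromosome 14, 53042428 to 53135678, mm10), 10 neighbouring variable segments held 246 of 2470 Trav UMIs in ALLO CD4 T-like cells, in 107 of 1060 cells, and 0 of 4212 in SYN. In CD8 T-like cells they held 151 of 1750 UMIs, in 75 of 800 cells, and 1 of 2132 in SYN. Trav14d-3-dv8 alone had 127 UMIs in 66 ALLO CD4 T-like cells. The like stretch with at most 1 UMI per segment in ALLO was 1 segment with 4 SYN UMIs. The presence of the stretch in both T cell classes and in many cells argues against a single expanded clone. Near copies outside the stretch, named by the same numbers, ran the other way as a set. They held 21.9% (20.7 to 23.2%) of 4220 Trav UMIs in ALLO and 29.9% (28.8 to 31.0%) of 6344 in SYN. Examples were Trav14n-3 at 65 ALLO and 241 SYN UMIs, Trav8n-2 at 31 and 112 and Trav13n-4 at 19 and 88. Not every copy did so, since Trav16n had 76 and 86 UMIs and Trav13-4-dv7 165 and 172, larger shares in ALLO. Summed with their copies, the segments of the stretch held 31.4% of Trav UMIs in ALLO and 29.9% in SYN. Trav6n-6, with no copy read, had 52 UMIs and 0. A germline difference between the animals and a different assignment of reads among near copies of these segments were not told apart.

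Droplets under 1000 UMIs were 36.3% of kept cells in SYN and 8.95% in ALLO, and unnamed clusters that carried B and T cell genes together or came over 90% from SYN held 37.4% and 3.31%. In the cluster left unnamed only for drawing over 90% of its cells from SYN, 17.0% of SYN droplets thinned to 500 UMIs held both B and T marker UMIs, 7.95 times (6.68 to 9.48) the 2.14% of named SYN B-like and T-like cells. Free or mixed RNA would give such a ratio, but the ratio cannot decide about it. The naming rule had left droplets of clusters with both gene sets out of the named cells, which lowers the reference share. Of the 3567 SYN droplets so left out, 45.4% (43.7 to 47.0%) held both. The ALLO droplets of the cluster tested were at 2.45% (0.673 to 6.16%). Doublets of whole cells are argued against for these droplets as a set, since the median was 689 UMIs in that cluster and 730 over all 6390 such SYN droplets against 3289 in named cells, a ratio of 0.222, but not for the 123 in T subclusters mixed with B genes, with a median of 5961 UMIs and a ratio of 1.81. Whether the shallow droplets may come from handling, from the spleen or from the authors' barcode calling stays open.

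For the higher cytotoxic genes of ALLO CD8 T-like cells, deeper ALLO cells are argued against, since median depths were 4835 UMIs in ALLO and 4875 in SYN. The median log2 ratio was 0.60 (0.32 to 0.87) in cells thinned to 1000 UMIs. Thinning keeps each gene's expected share of a cell, so that value says little about depth. NK receptor genes, summed, had a log2 ratio of −0.059 (−0.24 to 0.12), which alone leaves room for a small NK share because CD8 T-like cells carry these genes too, and with the largest NK share they allow, 2.72% of UMIs, taken out of ALLO alone the cytotoxic median fell to 0.0032 (−0.054 to 0.14). Over the 580 ALLO and 566 SYN CD8 T-like cells with a UMI of Cd8b1, found in 2.75% and 0.901% of NK-like cells, it was 0.78 (0.57 to 0.96), which argues against NK cells as the cause. The summed cytotoxic CPM went from 6199 in SYN to 8124 in ALLO, while its change in B-like cells was −0.0579% of that change, with an upper bound of 0.183%, which argues against free RNA. An effect of the allograft may underlie the pattern, as a hypothesis from 1 library per group that other differences between the animals leave open and untested.

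The 18 genes shifted alike in B-like, CD4 T-like and CD8 T-like cells were set against the same kind of explanation. In the library where they were higher, 13 of the 18 differed in CPM between classes beyond counting error. This cannot decide about free RNA. A like number of free UMIs per droplet gives a CPM that falls as depth rises, and the classes differ in depth. A gene made in 1 class and present as free RNA in the others would differ as well. Free RNA so stays open. Median depths were 3182.5 and 3075 UMIs in ALLO and SYN B-like cells, 3796 and 3814.5 in CD4 T-like and 4835 and 4875 in CD8 T-like cells. These like depths argue against depth as the whole cause. After thinning to 1000 UMIs 11 of the 18 stayed shifted at least 1.5-fold in all classes. Thinning keeps each gene's expected share of a cell, so this count says little about depth. A response to handling could raise Hspa1a and Hspa1b but cannot be told apart from other causes, because the immediate early list lay at percentiles of 99.98, 69.94 and 1.905 in the 3 classes and so points both ways. A genetic difference between the animals, which the Trav stretch bears on but which was not tested for genes such as Cdk5rap1, and an effect of the graft stay open.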
